A study of Mus musculus with 8 samples.

How the data were processed

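The data are 1 table of 24421 genes with 8 libraries: EGFP+ and tdTomato+ cells of 4 mice, 2 of them given UVB. RNA was made into libraries with a poly(A) selecting, unstranded kit from 1 µg of total RNA. Per the submitters' processing notes, reads were handled with FastQC, TopHat2 2.0.12, Cufflinks 2.2.1 and DESeq2 1.14.1 on mm10. The tool that counted reads per gene and the annotation it used are not given in the sources used here.

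The signal values analysed are normalized reads as deposited by the authors, per the file headers, with 1 column per library. Each column is a whole number of reads per gene divided by 1 size factor per library, as in DESeq2. Whole reads were recovered from them, and 195368 of 195368 values lay within 0.01 of a whole number (100%). The recovered factors ran from 0.701 to 1.20. Read totals were 16200359 and 13545505 for EGFP without UV, 16162492 and 13288698 for EGFP with UV, 15692661 and 11186363 for tdTomato without UV, and 16711981 and 16543913 for tdTomato with UV. Of the genes in the table, 3897 had 0 reads in every library and 27 had a date in place of a symbol. The table also holds log2 fold changes with their errors, a score, and a p-value and adjusted p-value per gene, all computed by the authors with DESeq2 for EGFP+ against tdTomato+ cells over all 8 libraries, per the file headers. Those log2, score and p-value columns were used only to compare with the values computed here. Columns were matched to libraries by their labels.

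The comparisons, tests, gene lists, naming rule and alternative settings were fixed before the data were examined. The plan named edgeR for raw counts and limma for normalized values. The deposited values are normalized, so limma was the test, and settings named for the scaling of raw counts did not apply. limma 3.58.1 in R 4.3.3 was run on log2 of the value plus 1, with a mean per group for all 8 libraries in 1 fit, empirical Bayes moderation with a trend, and 4 residual degrees of freedom (median of 8.4 after moderation). Genes with a mean of at least 1 in at least 1 group were tested, 18070 in all, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. The p values rest on the spread of 2 mice per group, pooled over groups. An exact permutation test of 2 against 2 cannot give p under 0.333 and was not used. Fold changes are given with the moderated standard error, and group values as means with the standard deviation over libraries.

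The 6 comparisons were EGFP+ against tdTomato+ over all mice, without UV and with UV, UV against no UV in EGFP+ and in tdTomato+ cells, and the difference between those UV changes. The 31 lists held 432 genes: melanin synthesis and melanosomes, melanocyte lineage regulators, MiT family, basal, suprabasal, stress and hair follicle keratinocyte, sebocyte, fibroblast and matrix, endothelial, pericyte and smooth muscle, skeletal muscle, macrophage and dendritic cell, neutrophil, T and NK cell, mast cell, Schwann cell and glia, adipocyte, erythrocyte, p53 targets, nucleotide excision repair, cell cycle, inflammatory cytokines, interferon response, immediate early and heat shock, paracrine factors acting on melanocytes, Wnt targets, lysosome and vacuolar ATPase, NRF2 targets, neural crest adhesion and axon guidance, and housekeeping. Lists with at least 3 tested members were tested by camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and repeated with an estimated correlation, under which 0 lists passed in any comparison. Counts of members are over all genes tested, and "over the list alone" means adjusted over the list alone. The values of 1 list member are not reported here.

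Genes were named by a rule. Mitf, Tyr and Kit were always given. Up to 4 members of a list with the smallest p were eligible, and so were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 in the higher group, no overlap between the libraries compared, and a symbol that is not a predicted gene. Where fewer than 3 genes were called, the 5 with the smallest p took that place. A gene with 0 reads in a group was given a bound from 3 reads over the group, and a gene with 1 to 3 reads a ratio with a 95% exact interval. These bounds and intervals cover counting error only.

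EGFP+ and tdTomato+ cells of a mouse were taken as a pair in an alternative fit with mouse as a block. Across genes, the deviation of a mouse from its group mean in EGFP+ cells correlated with that in tdTomato+ cells at 0.0873 for mice 1 and 2 and 0.0562 for mice 3 and 4. The block was kept as an alternative, as planned. By replicate number across the UV arms the correlations were 0.0549 in EGFP+ and 0.0759 in tdTomato+ cells. Replicate numbers in the UV and no UV arms belong to different mice. Other alternatives were quantile normalization, rescaling without the 20 most abundant genes, a pseudocount of 0.1, no filter, a stricter filter (at least 5 in 2 libraries), only the libraries compared, and each library left out in turn. Added after the data were examined were edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and voom on the recovered reads, and a fit without mouse 1.

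Simulated data with known changes were put through the same code. With 50 genes changed at each fold, a 4-fold change was recovered for 66% of genes in EGFP+ against tdTomato+ cells over all mice, 40% without UV, 44% with UV, 32% for UV in EGFP+ cells, 20% for UV in tdTomato+ cells and 10% for the difference between UV changes. A 16-fold change was recovered for 92%, 74%, 80%, 80%, 68% and 54%. Of the genes called, 5 of 131, 1 of 94, 3 of 99, 1 of 97, 7 of 74 and 0 of 52 were false. A 4-fold shift of the cell cycle list gave adjusted p = 2.52e-60 and 0 calls of other lists. Scarce or correlated genes may fare otherwise.

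Of the symbols in the table, 23350 are in the reference annotation GENCODE vM21 (GRCm38, mm10), which gave the positions. Among the genes named, 25 overlap another protein-coding gene, and in an unstranded library their reads could come from either: Atp6v1b2, Awat2, B2m, Bax, Car14, Ccnd1, Cdc20, Ctsa, Ctsd, Cxcl10, Dusp1, Gpx2, Hspa1a, Igfbp7, Irf1, Lgr5, Lrrc34, Rpl13a, Rtp4, Sqstm1, Syngr1, Tmod1, Tubb3, Txnrd1 and Xist.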

Results

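The skin of 4 C57BL/6J mice was studied, each carrying the ROSA mTmG reporter and Tyr:CreERT2. In this reporter a cell makes membrane tdTomato until Cre recombinase acts and membrane EGFP afterwards, and Tyr:CreERT2 is a tamoxifen-dependent Cre under tyrosinase regulatory sequence, which is active in the melanocyte lineage. Tamoxifen was given for 10 days from day 21 and the back was depilated on day 50. UVB at 150 mJ/cm2 was given for 3 days to 2 mice, 2 were mock treated, and skin was taken on day 54. EGFP+ cells (melanocytes) and tdTomato+ cells (the other skin cells) were sorted from every mouse, which gave 8 libraries in 4 groups of 2. Mice 1 and 2 are replicates 1 and 2 without UV, and mice 3 and 4 are replicates 1 and 2 with UV. The libraries held 11186363 to 16711981 reads and 11186 (UV EGFP replicate 2) to 17076 (no UV tdTomato replicate 2) detected genes. Across genes, which are not independent replicates, the 2 libraries of a group correlated at r = 0.960 (EGFP without UV), 0.925 (EGFP with UV), 0.923 (tdTomato without UV) and 0.955 (tdTomato with UV), and the highest correlation between an EGFP and a tdTomato library was 0.864. Xist, the RNA that silences an X chromosome in females, had 477 and 1103 reads in the libraries of mouse 1 and at most 4 in any other library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had at most 9 reads in the libraries of mouse 1 and at least 2253 in the others. The values are per gene, so the isoforms of Mitf were not told apart and are not analysed here.

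The genes that set EGFP+ cells apart from tdTomato+ cells over all 4 mice were led by pigment and keratinocyte genes. Mitf, the transcription factor that directs melanocyte identity, was 4.21 ± 0.30 (SE) log2 units higher in EGFP+ cells, at 4487 ± 1949 (SD, n = 4) against 239 ± 72.5 (SD, n = 4) normalized reads (limma adjusted p = 2.59e-05). Tyr, the rate-limiting enzyme of melanin synthesis, was higher by 5.16 ± 0.32 (26206 ± 5919 against 1083 ± 1028, n = 4 each, adjusted p = 1.36e-05). Kit, the receptor for stem cell factor, was higher by 5.63 ± 0.34 (4910.2 ± 713 against 167 ± 153, n = 4 each, adjusted p = 1.16e-05). Dct, which encodes dopachrome tautomerase, was higher by 5.80 ± 0.25 and reached 278696 ± 48045 normalized reads in EGFP+ cells. In the other direction, Krt14, a keratin of the basal epidermis, stood at -8.97 ± 0.16 (251 ± 61.2 against 125056 ± 16748, n = 4 each, adjusted p = 8.75e-08). Dcn, the fibroblast proteoglycan decorin, stood at -9.89 ± 0.34 (8.26 ± 3.44 against 8296 ± 897, n = 4 each, adjusted p = 9.87e-07). In the mm10 assembly Mitf spans 97807052 to 98021349 on the plus strand of chromosome 6, Tyr 87424771 to 87493512 on the minus strand of chromosome 7, Kit 75574916 to 75656722 on the plus strand of chromosome 5 and Dct 118012790 to 118052244 on the minus strand of chromosome 14. Of 18070 genes tested, 5217 differed at adjusted p under 0.05, 1746 higher and 3471 lower in EGFP+ cells. Under quantile normalization the split was 2857 higher and 2672 lower (51.7% higher in place of 33.5%), and with the values rescaled without the 20 most abundant genes it was 2655 higher and 2895 lower (47.8% higher). The median over genes moved by 0.57 and 0.25 log2 units. The count was 3463 without UV tdTomato replicate 1 and 3469 without no UV EGFP replicate 2.

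**Figure D1:**
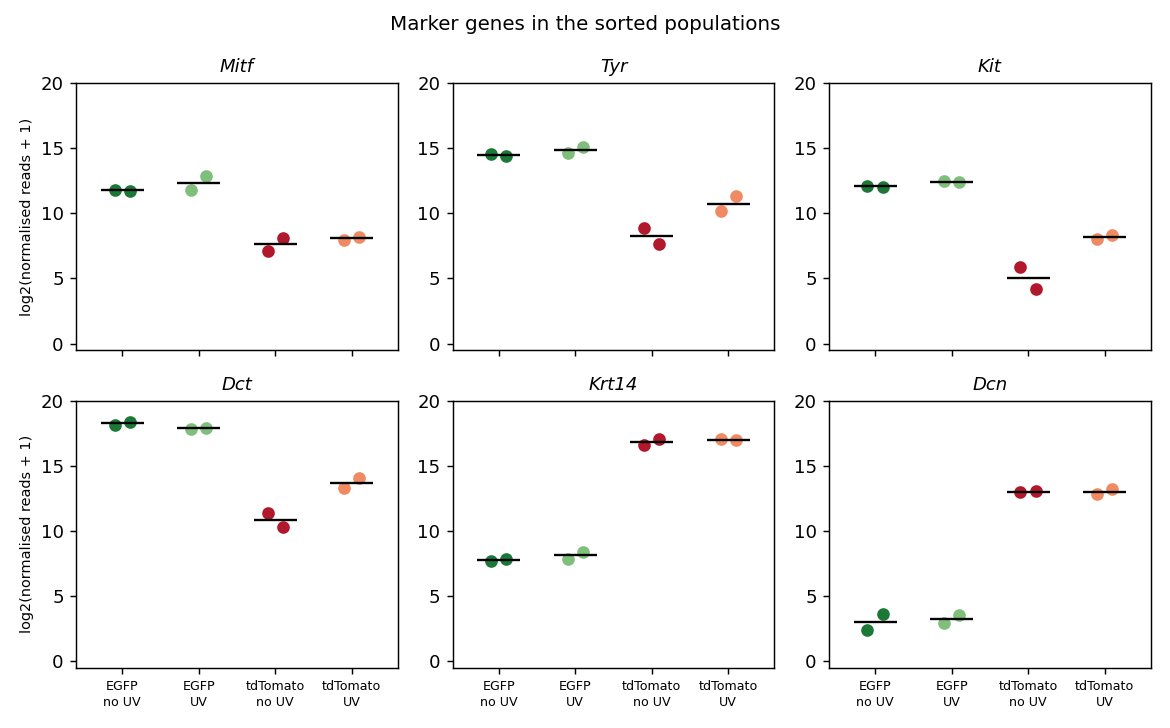
Normalized reads of marker genes in each of the 8 libraries, on a log2 scale after 1 is added, by population and UV treatment.

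Melanin genes were the highest list in EGFP+ cells. Mlana, a melanosome membrane protein, was higher by 5.50 ± 0.21 (19591 ± 8785 against 761 ± 804, n = 4 each), and Slc45a2, a melanosome transporter, by 5.97 ± 0.27. Syngr1, a vesicle protein placed on the same list, was higher by 5.06 ± 0.20. Trpm1, a channel gene activated by MITF, was higher by 6.62 ± 0.77. Among genes outside the list, the actin-capping gene Tmod1 was higher by 6.36 ± 0.66, the tetraspanin gene Tspan10 by 6.27 ± 0.58 and the semaphorin receptor gene Plxnc1 by 6.21 ± 0.56. Of 22 tested members of the list of melanin synthesis and melanosome genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone), with a median of 5.35 (camera adjusted p = 6.51e-19; adjusted p = 0.0614 with an estimated correlation). The lower member was Mreg, a melanosome transfer gene, at -1.53 ± 0.37 (adjusted p = 0.0140). Ednrb, the endothelin receptor of melanoblasts (5.82 ± 0.29), and Sox10, a neural crest transcription factor (5.81 ± 0.52), led the list of melanocyte lineage regulators. Of its 14 tested members 9 were higher and 1 lower (9 and 1 over the list alone). Its median was 3.01, with adjusted p = 6.03e-07 (adjusted p = 0.076 with an estimated correlation). The lower member there was Snai2, a transcription factor of migrating melanoblasts, at -1.51 ± 0.29 (adjusted p = 0.00481). In the MiT family of 4 related transcription factors, Mitf and Tfeb (3.31 ± 0.36) were higher, while Tfe3 (0.27 ± 0.29, adjusted p = 0.512) and Tfec (-0.78 ± 0.69, adjusted p = 0.446) did not pass (2 higher over the list alone as well; median 1.79, adjusted p = 0.0146; adjusted p = 0.201 with an estimated correlation). Tfec had 1 read in EGFP+ cells and 7 in tdTomato+ cells, a ratio of 7.87 (95% counting interval 1.01 to 354), and stood at 0.22 under quantile normalization. Members named because few of a list passed, or because they went against their list, were chosen after their values were seen. The call of Mreg was lost in 6 of 8 fits that each left out 1 library (adjusted p up to 0.109, without UV tdTomato replicate 1) and that of Snai2 in 4 (up to 0.069, without no UV tdTomato replicate 1). That of the MiT list was lost without UV tdTomato replicate 2 (0.0507) or when members shared with other lists were left out (0.164).

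Lysosome and neural crest genes were also higher in EGFP+ cells. Cd63, a tetraspanin of late endosomes and melanosomes, was higher by 2.27 ± 0.09, Atp6v1b2, a subunit of the proton pump, by 2.52 ± 0.12 and Sqstm1, an autophagy receptor, by 2.62 ± 0.13. Of 23 tested lysosome and vacuolar ATPase genes 13 were higher and 0 lower (14 and 1 over the list alone), with a median of 0.69 (adjusted p = 7.98e-09; adjusted p = 0.076 with an estimated correlation). Among neural crest adhesion and axon guidance genes, Nrcam (4.13 ± 0.44) and Ncam1 (2.93 ± 0.32), both cell adhesion molecules of neurons, were higher together with Cdh2, Cdh19 and Plxnc1, while the GDNF family receptor gene Gfra1 was lower at -5.03 ± 0.48. That list had 5 higher and 1 lower of 11 tested (6 and 1 over the list alone). The list median was 1.60, with adjusted p = 0.00382 (adjusted p = 0.118 with an estimated correlation). Schwann cell and glia genes split: Fabp7, a glial fatty acid carrier (4.44 ± 0.49), and Foxd3, a neural crest transcription factor (5.59 ± 0.73), were higher, and the myelin genes Mbp (-5.18 ± 0.59) and Mal and the neurotrophin receptor gene Ngfr were lower. Of 12 tested, 7 were higher and 3 lower (7 and 4 over the list alone). The median stood at 2.17, with adjusted p = 0.0208 (adjusted p = 0.523 with an estimated correlation). The call of the Schwann cell and glia list was lost without no UV EGFP replicate 1 (0.107) and without members shared with other lists (0.429). Calls of single genes were lost in 5 of 8 fits without 1 library for Mal (up to 0.0979, without no UV EGFP replicate 2) and Cdh19 (up to 0.118, without no UV EGFP replicate 1), and in 4 for Cdh2 (up to 0.0838, without UV tdTomato replicate 2).

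Keratinocyte genes were lower in EGFP+ cells. Krt5, the partner of Krt14 in the basal layer, stood at -8.99 ± 0.20 (86.2 ± 19.5 against 44233 ± 9538, n = 4 each), and led the basal keratinocyte genes. Krtdap (-8.79 ± 0.32) and Sbsn (-6.47 ± 0.34), both made in the upper epidermis, led the suprabasal and cornified keratinocyte genes. Krt17 (-8.92 ± 0.23; 108 ± 38.6 against 50821 ± 5532, n = 4 each) and Krt16 (-9.32 ± 0.38), keratins of injured and follicular epidermis, led the stress and wound keratinocyte genes. Among hair follicle keratinocyte genes, Cd34, a marker of bulge stem cells, stood at -9.44 ± 0.58 and Lgr5, a receptor of follicle stem cells, at -6.08 ± 0.41. Among sebocyte genes the lower members were Dgat2, an enzyme of triglyceride synthesis (-5.03 ± 0.88), Mgst1, Mc5r, Awat2 and Awat1, and Mc5r, the melanocortin receptor of sebaceous glands, had 0 reads in EGFP+ cells and was at least 21.5-fold lower, with all its tdTomato+ reads from mice without UV. In the basal keratinocyte list 1 gene was higher and 10 lower (1 and 10 over the list alone, median -6.36, adjusted p = 1.75e-07; adjusted p = 0.0788 with an estimated correlation), and the higher member was Cdh3, a cadherin of basal and matrix cells, at 1.84 ± 0.29 (adjusted p = 0.00175). In the suprabasal list 13 of 15 were lower (14 over the list alone). The members had a median of -6.47, with adjusted p = 1.05e-08 (adjusted p = 0.0866 with an estimated correlation). For the stress list the numbers were 9 of 13 (10 over the list alone). Their median was -7.40, with adjusted p = 8.63e-07 (adjusted p = 0.076 with an estimated correlation). For the hair follicle list they were 15 of 17 (15 over the list alone). Its median was -5.30, with adjusted p = 1.82e-07 (adjusted p = 0.0614 with an estimated correlation). For the sebocyte list they were 5 of 9 (8 over the list alone). The list median was -1.86, with adjusted p = 0.0138 (adjusted p = 0.345 with an estimated correlation). In the sebocyte list, calls of single genes were lost in 2 of 8 fits without 1 library for Dgat2 (up to 0.0612, without no UV tdTomato replicate 1), Mgst1 (up to 0.0659, without UV tdTomato replicate 2) and Awat1 (up to 0.0605, without UV EGFP replicate 2; 0.0603 with mouse as a block). The call of Awat2 was lost in 6 (up to 0.167, without UV tdTomato replicate 1) and that of Mc5r with edgeR and DESeq2 (adjusted p of 1 and 0.314).

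Other lower genes without a list of their own included Aqp3, the water and glycerol channel of keratinocytes (-9.85 ± 0.25), and Igfl3, an insulin-like growth factor family gene (-9.99 ± 0.50). Ifi202b, an interferon-inducible gene with near-identical copies that makes its read count uncertain, stood at -10.31 ± 0.57 with 2 reads in EGFP+ cells, a ratio of 3854 (1066 to 31830).

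Dermal, vascular and immune genes were lower in EGFP+ cells too. Postn, the matrix protein periostin, stood at -8.31 ± 0.55. Pecam1, the endothelial junction protein, stood at -5.87 ± 0.89, with 1 read against 541 (ratio 608, 109 to 24054), and Notch3, a receptor of mural cells, at -5.71 ± 0.75. Ptprc, the leukocyte antigen CD45, stood at -5.45 ± 0.96 and Cd74, the invariant chain of antigen presentation, at -4.97 ± 0.85. Il1r2, a decoy receptor of neutrophils, stood at -8.37 ± 0.71 (3 reads in EGFP+ cells, ratio 1408, 481 to 6830) and Cd3g, a T cell receptor subunit, at -5.87 ± 1.08 (2 reads, ratio 448, 124 to 3708). The fibroblast and matrix list had 1 gene higher and 12 lower of 16 tested (1 and 13 over the list alone, median -4.83, or -5.49 with genes at 0 reads placed at their bound; adjusted p = 1.83e-05; adjusted p = 0.0614 with an estimated correlation), the higher member being Fn1, the matrix protein fibronectin (1.45, adjusted p = 0.0157). In the endothelial list 6 of 12 were lower (9 over the list alone). The median stood at -3.33 (bound -3.35), with adjusted p = 0.0101 (adjusted p = 0.523 with an estimated correlation). Pericyte and smooth muscle genes had Cspg4, a proteoglycan of pericytes and of melanocytes, higher at 1.11 ± 0.25 (adjusted p = 0.011), and Notch3, Pdgfrb, Cnn1 (0 reads in EGFP+ cells, at least 47.5-fold), Des and Acta2 lower, of 10 tested (1 and 5 over the list alone). The members had a median of -3.28 (bound -3.81), with adjusted p = 0.0357 (adjusted p = 0.345 with an estimated correlation). Of 16 macrophage and dendritic cell genes 10 were lower (13 over the list alone). Their median was -3.82 (bound -4.06), with adjusted p = 0.00187 (adjusted p = 0.39 with an estimated correlation). The neutrophil list had Il1r2, Cxcr2, S100a9 and Camp lower (Camp with 0 reads in EGFP+ cells, at least 16.4-fold, all tdTomato+ reads from UV mice) of 9 tested (4 over the list alone). Its median was -2.24 (bound -2.30), with adjusted p = 0.0295 (adjusted p = 0.174 with an estimated correlation). Of 11 T and NK cell genes 8 were lower (8 over the list alone). The list median was -3.91 (bound -4.69), with adjusted p = 0.0223 (adjusted p = 0.523 with an estimated correlation).

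Several of these calls were lost when 1 library was left out. Fn1 lost its call in 5 of 8 fits without 1 library (adjusted p up to 0.111, without UV tdTomato replicate 1), Acta2 in 4 (up to 0.106, without no UV tdTomato replicate 1), Des in 4 (up to 0.0849, same library), and S100a9 in 4 (up to 0.0617, without UV tdTomato replicate 1). Cspg4 lost it in 3 (up to 0.0664, same library) and Cd74 in 1 (0.0649, without no UV tdTomato replicate 1). Camp lost its call with edgeR and DESeq2 (adjusted p of 1 and 0.376). Without no UV tdTomato replicate 1 the endothelial list had adjusted p = 0.138, the macrophage and dendritic cell list 0.0531, the T and NK cell list 0.185 and the pericyte list 0.0838. The pericyte list was also lost without no UV EGFP replicate 1 (0.107), UV EGFP replicate 1 (0.13) or no UV tdTomato replicate 2 (0.058), the T and NK cell list without no UV EGFP replicate 1 (0.093) or UV EGFP replicate 1 (0.101), and the neutrophil list without UV EGFP replicate 1 (0.0665).

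Muscle, mast cell, fat and red cell genes had few readable members. Myh1, a skeletal muscle myosin, stood at -3.27 ± 0.89 (adjusted p = 0.0244; 1 read in EGFP+ cells, ratio 86.5, 15.1 to 3461) and was the only member of the skeletal muscle list that passed, of 10 tested (0 over the list alone, median -0.79, bound -1.04; adjusted p = 0.705). Cma1, the mast cell chymase, stood at -2.36 ± 0.56 (adjusted p = 0.0133; 1 read, ratio 85.4, 14.9 to 3417) and was the only member that passed of 5 mast cell genes (1 over the list alone, median -0.95, bound -1.63; adjusted p = 0.436). Of 9 adipocyte genes Pparg, a regulator of fat cells, was higher by 1.90 ± 0.42 and Cidec, a lipid droplet protein, was lower with 0 reads in EGFP+ cells, at least 16.3-fold (1 and 1 over the list alone, median -0.07, bound -0.06, while the test pointed up with adjusted p = 0.523). The erythrocyte list had 2 tested members, with a median of -0.58, and was not tested. The calls were lost in 5 of 8 fits without 1 library for Myh1 (up to 0.109, without no UV tdTomato replicate 1) and Pparg (up to 0.0939, without no UV EGFP replicate 2), and with edgeR and DESeq2 for Cma1 (adjusted p of 1 and 0.261) and Cidec (0.0942 and 0.223).

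Inflammatory, immediate early and paracrine genes were lower in EGFP+ cells, and interferon genes moved in both directions. Cxcl1, a neutrophil-attracting chemokine, stood at -4.89 ± 0.23 and Ptgs2, the inducible cyclooxygenase, at -9.08 ± 0.61 (2 reads in EGFP+ cells, ratio 1762, 487 to 14554). Dusp1, a phosphatase that ends MAP kinase signals, stood at -3.83 ± 0.12 and Zfp36, which destabilizes cytokine RNA, at -3.24 ± 0.14. Edn1, the endothelin that acts on melanocytes, stood at -6.90 ± 0.71 (2 reads, ratio 369, 102 to 3054). Nrg1, a growth factor for melanocytes, stood at -7.04 ± 0.73 with 0 reads in EGFP+ cells, at least 413-fold. Bst2 (2.32 ± 0.23), Rtp4 (2.44 ± 0.26) and Ifit3 (4.62 ± 0.70), all induced by interferon, were higher, and Irf1, the interferon regulatory factor (-2.07 ± 0.19), and the chemokine gene Cxcl10 were lower. Of 19 inflammatory cytokine genes 15 were lower (16 over the list alone). The median stood at -5.72, with adjusted p = 1.62e-08 (adjusted p = 0.0614 with an estimated correlation). Of 16 immediate early and heat shock genes 11 were lower and 0 higher (12 and 1 over the list alone). The members had a median of -1.62, with adjusted p = 2.04e-05 (adjusted p = 0.162 with an estimated correlation). The list of paracrine factors acting on melanocytes had 1 higher and 9 lower of 12 (1 and 9 over the list alone, median -3.79, bound -5.03; adjusted p = 0.00075; adjusted p = 0.076 with an estimated correlation), and the higher member was Pomc, the precursor of melanocortins (3.04, adjusted p = 0.0231). Interferon response genes had 6 higher and 2 lower of 18 (7 and 2 over the list alone). Their median was 1.02, with adjusted p = 0.00187 (adjusted p = 0.345 with an estimated correlation). Pomc lost its call in 4 of 8 fits without 1 library (up to 0.0834, without UV tdTomato replicate 1) and Cxcl10 in 7 (up to 0.171, without no UV EGFP replicate 1).

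Cell cycle and p53 target genes were lower in EGFP+ cells, and repair genes were near 0. Cdc20, an activator of mitotic exit, stood at -2.76 ± 0.30 and Mki67, the Ki-67 antigen, at -3.41 ± 0.56. Perp, a desmosome gene and p53 target, stood at -9.01 ± 0.26 and Pmaip1, a cell death gene, at -4.87 ± 0.36, while Bax, another cell death gene, was the only p53 target that was higher (0.77, adjusted p = 0.00183). Of 25 cell cycle genes 14 were lower (22 over the list alone). Their median was -3.06, with adjusted p = 3.64e-05 (adjusted p = 0.473 with an estimated correlation). Of 24 p53 targets 1 was higher and 9 lower (2 and 11 over the list alone). The list median was -1.15, with adjusted p = 0.0192 (adjusted p = 0.345 with an estimated correlation). In the nucleotide excision repair list, the TFIIH subunit genes Gtf2h1 (1.44 ± 0.16) and Gtf2h3 (-1.09 ± 0.19) were the only 2 of 20 that passed (1 and 1 over the list alone, median -0.09, while the test pointed up with adjusted p = 0.567). The p53 list lost its call without no UV tdTomato replicate 1 (0.22), no UV tdTomato replicate 2 (0.107) or UV tdTomato replicate 2 (0.0556) and without members shared with other lists (0.0689), and Mki67 without no UV tdTomato replicate 1 (0.0548).

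Wnt, NRF2 and housekeeping genes had no list call. Lgr5 and Ccnd1, the cyclin of the G1 phase (-2.95 ± 0.38), were lower with Rnf43, Lgr6 and Notum, and the Wnt targets Axin2 and Sp5 were higher, of 11 Wnt genes tested (2 and 5 over the list alone, median -0.59, adjusted p = 0.459). Gpx2, a glutathione peroxidase of epithelia, stood at -6.16 ± 0.46 and was lower with Nqo1 and Gclm, and Txnrd1, a thioredoxin reductase, was higher by 1.28 ± 0.16 with Gclc and Gstm1, of 13 NRF2 target genes (4 and 3 over the list alone, median -0.10 and mean -0.98, while the test pointed up with adjusted p = 0.424). Gusb, a lysosomal enzyme used as a reference gene (1.56 ± 0.24), Sdha and B2m were higher and Hprt (-0.66 ± 0.13) and Rpl13a were lower, of 12 housekeeping genes (3 and 3 over the list alone, median -0.02, mean 0.14, adjusted p = 0.445). Calls were lost in at least 1 of 8 fits without 1 library for Sp5 (up to 0.0664, without no UV EGFP replicate 2), Notum (0.0732, without no UV EGFP replicate 1), Gclm (0.137, without UV tdTomato replicate 2), Sdha (0.0502, without no UV tdTomato replicate 1), B2m (0.079, without no UV tdTomato replicate 2) and Rpl13a (0.0744, without UV tdTomato replicate 2).

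Some calls between EGFP+ and tdTomato+ cells depended on mouse 1 or on the setting. Without mouse 1 the count was 4768, with 2663 shared, and the calls of Rtp4 (0.0503), Pecam1 (0.0618), Ptprc (0.055), Cd3g (0.134), Cd74 (0.125), Dgat2 (0.165), Mki67 (0.0927), Ccnd1 (0.0731), Cdh3 (0.0653), Ngfr (0.0667), Gclc (0.0653), Gstm1 (0.0696) and Nqo1 (0.0748) were lost. So were those of Mreg (0.14), Snai2 (0.113), Fn1 (0.116), Pomc (0.107), Awat1 (0.0523), Awat2 (0.0808), Des (0.199), Acta2 (0.226), S100a9 (0.152), Myh1 (0.233), Pparg (0.125), Cxcl10 (0.316), Sp5 (0.126), Notum (0.0776), Gclm (0.0718), Sdha (0.138), B2m (0.109) and Rpl13a (0.0898). Lists lost without mouse 1 were MiT (0.0902), sebocyte (0.0596), endothelial (0.351), pericyte (0.208), macrophage and dendritic cell (0.152), T and NK cell (0.457), p53 (0.399) and immediate early (0.103). Quantile normalization ended the calls of Myh1 (0.11), Cma1 (0.0823), Awat1 (0.285), Awat2 (0.0811), Camp (0.0506), Cidec (0.0648) and Rpl13a (0.061). A pseudocount of 0.1 ended those of Pomc (0.059), Cma1 (0.064), Awat1 (0.0973) and Awat2 (0.0728), and rescaling without the 20 most abundant genes those of Cxcl10 (0.0815) and Gclm (0.104). On recovered reads Awat1 was lost with edgeR (1), DESeq2 (0.52) and voom (0.121) and Awat2 with edgeR (0.0732).

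**Figure D2:**
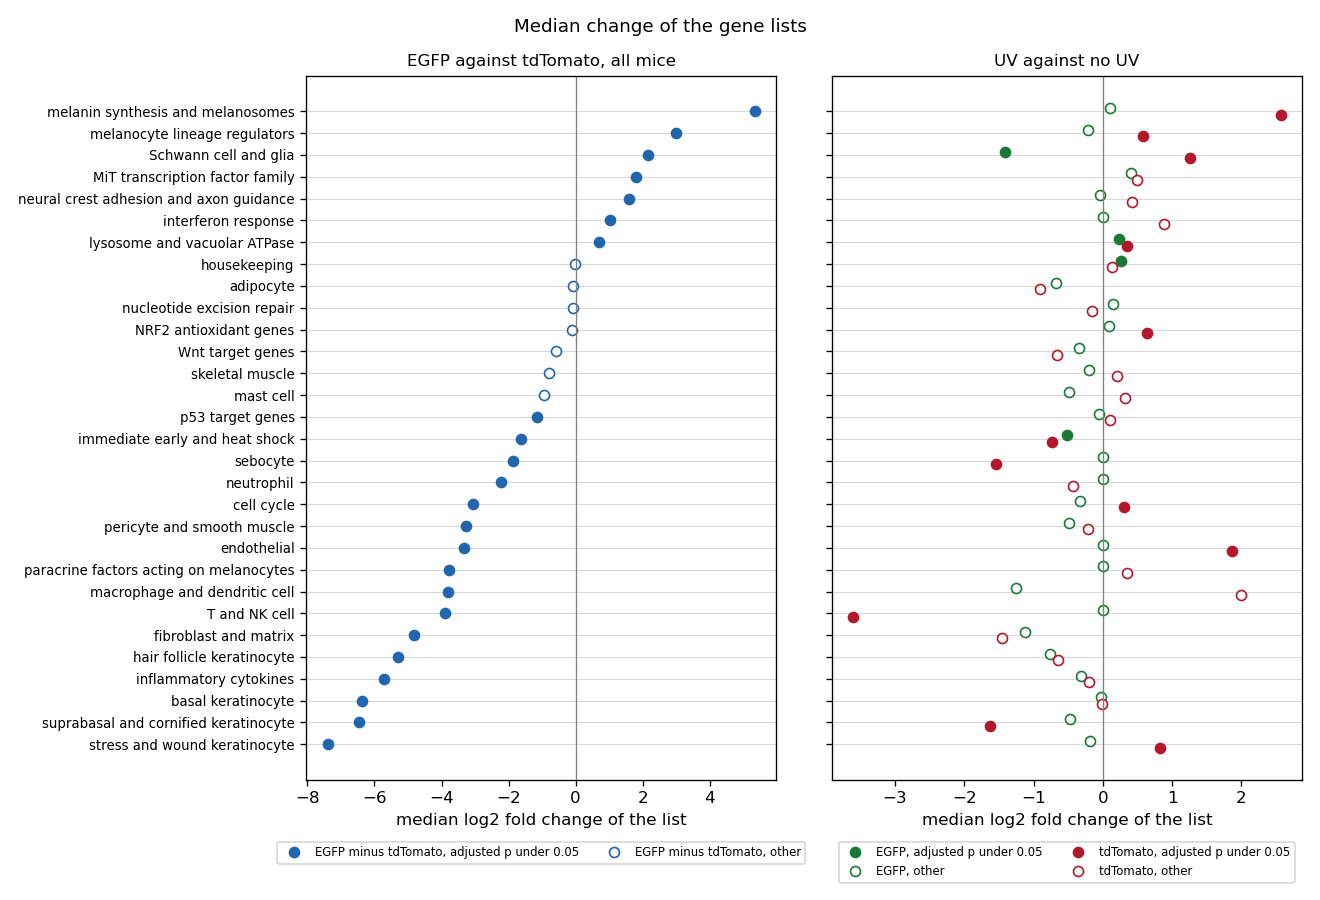
Median log2 fold change of each gene list in the comparisons of EGFP+ with tdTomato+ cells and in the comparisons of UV with no UV.

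The deposited table of the authors holds the same comparison of EGFP+ with tdTomato+ cells, with a log2 fold change of 4.20 for Mitf, 4.49 for Tyr, 4.74 for Kit, 5.03 for Dct, -8.93 for Krt14 and -9.93 for Dcn. The deposited values come from a model of read counts and those above are differences of mean logs. At adjusted p under 0.05 the deposited table has 5424 genes, 1942 higher and 3482 lower in EGFP+ cells, and 4665 of them also passed here, all 4665 in the same direction.

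In mice without UV the same pigment genes were higher in EGFP+ cells. Mitf was higher by 4.16 ± 0.42 (adjusted p = 0.000371), Tyr by 6.22 ± 0.45 (adjusted p = 7.05e-05) and Kit by 7.05 ± 0.48 (adjusted p = 5.43e-05; n = 2 per group). The largest rises included those of Wscd1, a sulfotransferase gene (8.97 ± 0.76, 2 reads in tdTomato+ cells, ratio 847, 234 to 7001), Car14, a carbonic anhydrase (8.66 ± 1.12), Trpm1 (8.64 ± 1.09), Plxnc1 (8.47 ± 0.79), Ednrb (8.09 ± 0.42), Tspan10 (8.03 ± 0.83) and Fam71f1 (7.80 ± 0.96, 0 reads in tdTomato+ cells, at least 129-fold). The largest falls included those of Col17a1, a hemidesmosome collagen (-11.33 ± 0.66), Plbd1, a phospholipase-like gene (-11.01 ± 0.70, 0 reads in EGFP+ cells, at least 1597-fold), and Ifi202b (-10.78 ± 0.80, 1 read, ratio 5306, 952 to 209636). Scel, a precursor of the cornified envelope, stood at -10.49 ± 0.57 (3.15 ± 0.925 against 6272 ± 3098, n = 2 each). Clca3a2, a chloride channel accessory gene, stood at -10.44 ± 0.75 (6.24 ± 0.589 against 10072 ± 856, n = 2 each) and Serpinb2, a protease inhibitor of keratinocytes, at -10.43 ± 0.53 (7.07 ± 0.587 against 11220 ± 1797, n = 2 each, adjusted p = 1.66e-05). Melanin genes had 17 higher and 0 lower of 22 (18 and 0 over the list alone, median 6.61, adjusted p = 6.38e-20; adjusted p = 0.0615 with an estimated correlation), and suprabasal keratinocyte genes 13 lower of 15 (14 over the list alone). The median stood at -7.54, with adjusted p = 1.62e-10 (adjusted p = 0.0743 with an estimated correlation). In the lineage list 8 were higher and Tfap2a, a transcription factor of the neural crest and of keratinocytes, was lower at -1.41 (9 and 2 over the list alone). The members had a median of 3.50, with adjusted p = 6.08e-07 (adjusted p = 0.0743 with an estimated correlation). Cdh3 was higher by 2.61 in a basal keratinocyte list with 9 lower (1 and 11 over the list alone). Their median was -5.94, with adjusted p = 2.12e-08 (adjusted p = 0.0743 with an estimated correlation). Cell cycle genes had Cdc20 and Mki67 lower of 25 (2 over the list alone). Their median was -2.29, with adjusted p = 0.00413 (adjusted p = 0.614 with an estimated correlation). Of 18070 genes 3468 differed, 1206 higher and 2262 lower, with 2013 higher and 1909 lower under quantile normalization (51.3% in place of 34.8% higher, median moved by 0.39) and 1804 higher and 1806 lower without the 20 most abundant genes (median moved by 0.30).

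The count without UV was 1398 without no UV EGFP replicate 2, 2016 without no UV EGFP replicate 1 and 2107 without no UV tdTomato replicate 2. Mouse 1, which carried Xist reads, was also left out as a whole. That leaves 1 EGFP and 1 tdTomato library without UV, so the spread within groups comes from the mice with UV alone. It gave 3109 genes, 1164 of them shared with the 3468, and an Mitf value of 3.59 (adjusted p = 0.0742). The calls of Car14 (0.0532) and Trpm1 (0.0535) were lost without no UV EGFP replicate 1 and that of Clca3a2 without mouse 1 (0.0521). Those of Tfap2a (adjusted p up to 0.195, without no UV EGFP replicate 1), Cdh3 (0.0703, without no UV EGFP replicate 2), Cdc20 (0.0907, without no UV tdTomato replicate 1) and Mki67 (0.141, without no UV EGFP replicate 2) were each lost in at least 2 of 4 such fits, and that of the cell cycle list without no UV EGFP replicate 2 (0.397) or no UV tdTomato replicate 1 (0.554) or mouse 1 (0.0778).

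In mice given UVB, pigment genes were again higher in EGFP+ cells and keratinocyte genes lower. Mitf was higher by 4.25 ± 0.42 (adjusted p = 0.000404), Tyr by 4.09 ± 0.45 (adjusted p = 0.000712) and Kit by 4.22 ± 0.48 (adjusted p = 0.000807; n = 2 per group). The largest rises included those of Lrrc34, a leucine-rich repeat gene (6.66, adjusted p = 0.00541), Smtnl1, a smoothelin-like gene (6.45 ± 1.03, 0 reads in tdTomato+ cells, at least 63.5-fold), Tmod1 (6.05 ± 0.93) and Cdh6, a cadherin (5.93 ± 0.99, 0 reads, at least 43.5-fold). The largest falls included those of Krt16 (-10.74 ± 0.54, 4.55 ± 1.87 against 10072 ± 5796, n = 2 each, adjusted p = 1.38e-05) and Il24, a cytokine of wounded epidermis (-10.67 ± 0.83, 0 reads in EGFP+ cells, at least 1156-fold). Igfbp7, a secreted binding protein, stood at -10.59 ± 1.07 (3 reads, ratio 2172, 743 to 10533), Dsc3, a desmosomal cadherin, at -10.42 ± 0.81, Lypd3, a surface protein of upper keratinocytes, at -10.07 ± 0.50, and Epgn, a ligand of the EGF receptor, at -10.06 ± 0.56 (7.25 ± 1.94 against 8728 ± 907, n = 2 each). Melanin genes had 18 higher of 22 with Mreg lower at -1.86 (20 and 2 over the list alone, median 4.04, adjusted p = 7.88e-18; adjusted p = 0.0637 with an estimated correlation), and the lineage list 7 higher with Snai2 lower at -2.02 (9 and 1 over the list alone). The list median was 2.02, with adjusted p = 1.13e-06 (adjusted p = 0.0732 with an estimated correlation). Stress keratinocyte genes had 9 lower of 13 (9 over the list alone, median -7.87, bound -7.92; adjusted p = 2.17e-07; adjusted p = 0.0732 with an estimated correlation) and inflammatory cytokine genes 15 lower (15 over the list alone). The median stood at -5.79, with adjusted p = 2.36e-09 (adjusted p = 0.0637 with an estimated correlation). Lysosome genes had 9 higher with Ctsd, the protease cathepsin D, lower at -1.08 (11 and 1 over the list alone). The members had a median of 0.59, with adjusted p = 2.17e-07 (adjusted p = 0.0983 with an estimated correlation). Of 18070 genes 3240 differed, 909 higher and 2331 lower, with 1378 higher and 1674 lower under quantile normalization (45.2% in place of 28.1% higher, median moved by 0.55) and 1285 higher and 2011 lower without the 20 most abundant genes (39.0% higher, median moved by 0.21). The count was 993 without UV tdTomato replicate 1, 1350 without UV tdTomato replicate 2, 2055 without UV EGFP replicate 2, 4952 without UV EGFP replicate 1 and 1992 when only the compared libraries were fitted. Lrrc34 lost its call without UV tdTomato replicate 1 (0.0678), and Mreg (up to 0.284), Snai2 (up to 0.145) and Ctsd (up to 0.146) lost theirs in 3 of 4 such fits. Mreg, which stood at -1.10 without UV EGFP replicate 1, also lost its call with a pseudocount of 0.1 (0.0544), without the 20 most abundant genes (0.0511), with only the compared libraries (0.105) and with edgeR (0.0517). With only the compared libraries Snai2 lost its call too (0.0552).

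The comparisons with and without UV shared 589 genes higher in EGFP+ cells, where 60.7 would be shared if calls in each were placed without regard to the other, and 1436 lower genes, where 292 would be.

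In EGFP+ cells 3 genes fell after UV, and 0 rose. Col6a1, a collagen chain of the dermis, fell by 6.24 ± 0.63 log2 units (102 ± 2.71 to 0.419 ± 0.593, n = 2 each, adjusted p = 0.0375; 1 read after UV, ratio 215, 38.3 to 8543). Crabp2, a retinoic acid carrier, fell by 6.19 ± 0.54 (470 ± 314 to 4.97 ± 2.46, n = 2 each, adjusted p = 0.018). Ptn, the growth factor pleiotrophin, fell by 5.80 ± 0.46 (665 ± 411 to 10.1 ± 3.56, n = 2 each, adjusted p = 0.0161). The values of the 3 genes in EGFP+ cells without UV were 9.34% to 19.7% of those in tdTomato+ cells of the same treatment. Mitf (0.57 ± 0.42, adjusted p = 0.668), Tyr (0.36 ± 0.45, adjusted p = 0.840) and Kit (0.35 ± 0.48, adjusted p = 0.866) did not pass. Without UV EGFP replicate 2 Mitf was at 0.05 and Tyr at 0.11, and without UV EGFP replicate 1 at 1.09 and 0.62. Mlana stood at 1.12 ± 0.30 (adjusted p = 0.282). Also not passing were H2-Aa, a class II antigen chain (-6.23 ± 0.79, adjusted p = 0.073), Col6a2, a second chain of the same collagen (-5.90 ± 0.83, 0 reads after UV, at least 45.5-fold, adjusted p = 0.079), Phlda3, a p53 target (2.08 ± 0.28, adjusted p = 0.079), and Fn1 (3.18 ± 0.50, adjusted p = 0.101). At unadjusted p under 0.05 limma had 1875 genes, and at adjusted p under 0.05 edgeR had 4, voom 0 and DESeq2 350. The limma count was 0 without no UV EGFP replicate 1, no UV EGFP replicate 2 or UV EGFP replicate 2, 1604 without UV EGFP replicate 1 (with Col6a1, Crabp2 and Ptn among them), 818 without mouse 1 (0 shared), 16 under quantile normalization, 1 with a pseudocount of 0.1 and 0 when only the compared libraries were fitted. The pseudocount ended the calls of Col6a1 (0.0785) and Crabp2 (0.0515). Without mouse 1 Col6a1 had adjusted p = 0.0863, Crabp2 0.092 and Ptn 0.0563. Quantile normalization gave Fn1 (0.0461), H2-Aa (0.0461), Zfp36 (0.0226) and Phlda3 (0.0254) a call. With DESeq2 these 4 passed, as did Col6a2, Mlana, Mbp, Ngfr, Ctsa and the p53 targets Bax (1.04 ± 0.17, limma adjusted p = 0.114) and Eda2r (4.06 ± 0.87, limma adjusted p = 0.177).

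In EGFP+ cells 4 lists passed after UV, with 0 members called in any of them. Quantile normalization moved the median over all genes by 0.27 log2 units. Zfp36 stood at -1.41 ± 0.20 and Nr4a1, a nuclear receptor gene switched on by stimulation, at -1.38 ± 0.38 (-0.71 without UV EGFP replicate 1), in a list with a median of -0.52 and 0 of 16 members called (0 higher and 1 lower over the list alone; adjusted p = 0.00303; adjusted p = 0.668 with an estimated correlation). Ctsa, the protective protein of lysosomes, stood at 0.88 ± 0.21 in a lysosome list with a median of 0.23 (0 called, and 0 over the list alone; adjusted p = 0.0114; adjusted p = 0.668 with an estimated correlation). Housekeeping genes had a median of 0.26 (0 called; adjusted p = 0.0431; adjusted p = 0.759 with an estimated correlation) and B2m, a chain of class I antigens, stood at 0.49 ± 0.22 (0.17 without no UV EGFP replicate 2, 0.31 without UV EGFP replicate 2, 0.81 without no UV EGFP replicate 1). Schwann cell and glia genes had a median of -1.41 (0 called, 2 lower over the list alone; adjusted p = 0.0466; adjusted p = 0.862 with an estimated correlation), with Mbp (-5.63 ± 0.83; 0 reads after UV, at least 37.5-fold, adjusted p = 0.0863) and Ngfr (-3.89 ± 1.11; 0 reads, at least 9.91-fold, adjusted p = 0.305). The p53 targets had adjusted p = 0.178 and the melanin genes a median of 0.11 with adjusted p = 0.105. The calls were lost without UV EGFP replicate 1 for all 4 lists (immediate early 0.941, lysosome 0.0538, housekeeping 0.0849, Schwann 0.253), without UV EGFP replicate 2 for lysosome (0.128), housekeeping (0.368) and Schwann (0.0858), without no UV EGFP replicate 1 for lysosome (0.138) and Schwann (0.337), and without no UV EGFP replicate 2 for immediate early (0.0868) and housekeeping (0.583). Quantile normalization ended those of the lysosome (0.668) and housekeeping (0.689) lists, and leaving out mouse 1 those of the immediate early (0.122), lysosome (0.193) and Schwann (0.52) lists.

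In tdTomato+ cells melanocyte genes rose after UV. Mlana rose by 3.49 ± 0.30 log2 units (121 ± 33.7 to 1401 ± 550.2, n = 2 each, adjusted p = 0.0101), Tyrp1, a melanosomal enzyme, by 4.21 ± 0.52 (580 ± 444 to 9694 ± 5018, n = 2 each, adjusted p = 0.0211), Ednrb by 4.45 ± 0.42 (28.6 ± 16.2 to 596 ± 12.8, n = 2 each, adjusted p = 0.0101) and Kit by 3.18 ± 0.48 (adjusted p = 0.0356). Syngr1 (2.64 ± 0.28), Mlph, a carrier of melanosomes (3.33 ± 0.41), and Plxnc1 (4.80 ± 0.79) rose as well. Tyr stood at 2.49 ± 0.45 (adjusted p = 0.0617), Sox10 at 3.32 ± 0.74 (adjusted p = 0.106; 1.95 without no UV tdTomato replicate 2) and Mitf at 0.48 ± 0.42 (adjusted p = 0.646), and Mitf had a value of -0.04 without no UV tdTomato replicate 1. Of 22 melanin genes 8 rose and 0 fell (13 and 1 over the list alone). Their median was 2.57, with adjusted p = 1.31e-13 (adjusted p = 0.254 with an estimated correlation). The lineage list had Kit and Ednrb higher of 14 (5 and 1 over the list alone). Its median was 0.58, with adjusted p = 0.00282 (adjusted p = 0.31 with an estimated correlation). The median melanin gene in tdTomato+ cells stood at 1.62% and 0.969% of its level in EGFP+ cells in the libraries without UV and at 4.08% and 8.42% in those with UV. The lineage list lost its call without UV tdTomato replicate 2 (0.179).

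Differentiation keratins fell in tdTomato+ cells after UV and a wound keratin rose. Krt10, a keratin of the suprabasal layers, fell by 4.95 ± 0.37 (15377 ± 4267 to 512 ± 228, n = 2 each, adjusted p = 0.0101) and Krt1, its partner, fell by 7.98 ± 0.80 (8236 ± 3341 to 35.4 ± 26.4, n = 2 each, adjusted p = 0.0133). Krt6a, a keratin of wounded epidermis whose near-identical copy Krt6b makes its read count uncertain, rose by 3.79 ± 0.52 (2265 ± 1099.8 to 30705 ± 12007, n = 2 each, adjusted p = 0.0292), and Krt16 stood at 2.29 ± 0.54 (1884 ± 72.5 to 10072 ± 5796, n = 2 each, adjusted p = 0.124). Krt1 and Krt10 were the members that passed of 15 suprabasal genes (5 lower over the list alone). The list median was -1.63, with adjusted p = 2.01e-05 (adjusted p = 0.31 with an estimated correlation). Krt6a was the member that passed of 13 stress genes (3 higher over the list alone). The median stood at 0.82, with adjusted p = 0.0386 (adjusted p = 0.519 with an estimated correlation). Mc5r fell by 4.92 ± 0.73, with 0 reads after UV and at least 21.3-fold, in a sebocyte list with a median of -1.54 (3 lower of 9 over the list alone; adjusted p = 0.00122; adjusted p = 0.392 with an estimated correlation). Basal keratinocyte genes had a median of -0.01 (adjusted p = 0.833). The stress list lost its call without no UV tdTomato replicate 1 (0.0841), no UV tdTomato replicate 2 (0.387) or UV tdTomato replicate 1 (0.356).

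Immune genes of tdTomato+ cells moved in both directions after UV. Cd207, the langerin of Langerhans cells, fell by 9.18 ± 1.13 (754 ± 683 to 0 reads, n = 2 each, at least 546-fold, adjusted p = 0.0211). C1qa, a complement gene of macrophages, rose by 5.98 ± 0.99 (0 reads without UV, at least 50.6-fold, adjusted p = 0.0476), Camp, the cathelicidin of neutrophils, by 4.54 ± 0.72 (0 reads, at least 13.0-fold, adjusted p = 0.0391), and Cma1 by 5.16 ± 0.79 (0 reads, at least 20.1-fold, adjusted p = 0.0375). The T cell gene Cd3e (-4.58 ± 1.39, adjusted p = 0.208) and the cytotoxic granule gene Nkg7 (-6.27 ± 1.54, adjusted p = 0.137) did not pass (-2.41 and -3.95 without UV tdTomato replicate 2), but T and NK cell genes fell as a list (0 of 11 called, 3 lower over the list alone). The members had a median of -3.60 (bound -3.77), with adjusted p = 0.000275 (adjusted p = 0.528 with an estimated correlation). Macrophage and dendritic cell genes had C1qa higher and Cd207 lower of 16 (3 and 3 over the list alone, median 2.00, adjusted p = 0.145), neutrophil genes a median of -0.44 (bound -0.05; adjusted p = 0.79) and mast cell genes a median of 0.32 (adjusted p = 0.302). Cxcl10, a chemokine for T cells, fell by 3.47 ± 0.45 (5883 ± 245 to 530.4 ± 17.0, n = 2 each, adjusted p = 0.0255) in an interferon list with a median of 0.88 (2 and 1 over the list alone; adjusted p = 0.191). The T and NK cell list lost its call without no UV tdTomato replicate 1 (0.195).

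Stress and signalling genes of tdTomato+ cells also changed after UV. Hspa1b, a heat shock chaperone whose near-identical copy Hspa1a makes its read count uncertain, fell by 2.87 ± 0.27 (10037 ± 2495 to 1348 ± 27.7, n = 2 each, adjusted p = 0.0101), and Hspa1a stood at -2.27 ± 0.46 (adjusted p = 0.0845). Ccng1, a p53 target, rose by 1.55 ± 0.26 (adjusted p = 0.0476), Atp6v1b2 by 1.38 ± 0.17, Cd63 by 1.06 ± 0.13 and Ctsd by 1.67 ± 0.22, while Gstm1, a glutathione transferase, fell by 1.62 ± 0.20. Immediate early and heat shock genes fell as a list with Hspa1b the member that passed (8 lower over the list alone). Their median was -0.74, with adjusted p = 9.29e-09 (adjusted p = 0.254 with an estimated correlation). Lysosome genes rose with Atp6v1b2, Cd63 and Ctsd passing (9 over the list alone). Their median was 0.34, with adjusted p = 7.07e-08 (adjusted p = 0.254 with an estimated correlation). NRF2 targets rose as a list (median 0.64, adjusted p = 0.00571; adjusted p = 0.304 with an estimated correlation) although Gstm1, the only member that passed, fell (3 and 1 over the list alone), and Gpx2 stood at 3.26 ± 0.65 (adjusted p = 0.0823). Cell cycle genes rose as a list (median 0.31, 0 called and 1 higher over the list alone, adjusted p = 0.0221; adjusted p = 0.649 with an estimated correlation), with the replication helicase gene Mcm4 at 0.89 ± 0.20. Endothelial genes (median 1.87, adjusted p = 0.0216; adjusted p = 0.649 with an estimated correlation), with the junction gene Cdh5 at 3.60 ± 1.34 (2.12 without no UV tdTomato replicate 2, 2.11 without UV tdTomato replicate 1), and Schwann cell and glia genes (median 1.26, adjusted p = 0.0262; adjusted p = 0.649 with an estimated correlation) rose as lists with 0 members called. The p53 targets had a median of 0.10 (adjusted p = 0.212), with Phlda3 at 1.16 ± 0.28, and the paracrine factors a median of 0.36 (bound 0.02; adjusted p = 0.33), with Nrg1 at 4.03 ± 1.03. Calls of lists were lost without no UV tdTomato replicate 2 for the endothelial (0.372), Schwann (0.996) and cell cycle (0.325) lists, without UV tdTomato replicate 1 for the endothelial (0.89) and Schwann (0.172) lists, and without UV tdTomato replicate 2 for the Schwann (0.0787), NRF2 (0.0951) and cell cycle (0.183) lists. The Schwann list was also lost without members shared with other lists (0.189).

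Genes outside the lists also changed in tdTomato+ cells after UV. Chil3, a chitinase-like protein of activated macrophages, rose by 8.66 ± 1.04 (0 reads without UV, at least 263-fold) and Slc38a5, an amino acid transporter, by 6.88 ± 0.91 (0 reads, at least 67.8-fold). Tubb3, a tubulin of neurons and melanocytes, rose by 6.10 ± 0.87 (0 reads, at least 43.8-fold), Mmp13, a collagenase, by 5.46 ± 0.75 (0 reads, at least 24.9-fold) and Serpine2, a protease inhibitor, by 5.31 ± 0.45 (236 ± 174 to 8045 ± 559, n = 2 each, adjusted p = 0.0101). Mt4, a metallothionein of squamous epithelia, fell by 9.35 ± 1.05 (1 read after UV, ratio 1959, 351 to 77443), Skint9 fell by 8.21 ± 1.04 (1 read, ratio 982, 176 to 38845), and Skint5 fell by 7.36 ± 0.91 (0 reads, at least 135-fold). Serpinb7, a protease inhibitor of upper epidermis, fell by 7.98 ± 0.99 (2 reads, ratio 581, 160 to 4801), H2-M2, a class I antigen gene of Langerhans cells, fell by 7.94 ± 1.16 (0 reads, at least 262-fold). Cps1, a urea cycle enzyme, fell by 6.86 ± 1.07 (0 reads, at least 83.2-fold). Skint5 and Skint9 belong to a family of near-identical genes made in keratinocytes, which makes their read counts uncertain. Of 18070 genes tested, 101 changed, 63 up and 38 down, and 2429 had unadjusted p under 0.05. Quantile normalization gave 218 genes (median moved by 0.06), edgeR 91, voom 228, DESeq2 619, a pseudocount of 0.1 gave 29, and fitting only the compared libraries gave 183. The limma count was 0 without UV tdTomato replicate 1 and 0 without UV tdTomato replicate 2, so the call of each gene named for this comparison was lost in both. It was 1772 without no UV tdTomato replicate 1 (85 of the 101 among them), 77 without no UV tdTomato replicate 2 (22 shared) and 2006 without mouse 1 (60 shared).

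The UV calls of named genes in tdTomato+ cells also depended on the setting. A pseudocount of 0.1 ended those of Kit (0.0765), Krt6a (0.0661), Mc5r (0.0794), Cd207 (0.0794), C1qa (0.0794), Camp (0.0871), Cma1 (0.112), Ccng1 (0.0794), Cxcl10 (0.0582), Ctsd (0.0582), Plxnc1 (0.106), Chil3 (0.0776), Slc38a5 (0.106), Mmp13 (0.074), Mt4 (0.072), Skint9 (0.12), Skint5 (0.059), Serpinb7 (0.118), H2-M2 (0.103) and Cps1 (0.0905). Without mouse 1 those of Mlana (0.0519), Mlph (0.0744), Krt1 (0.0521), Krt6a (0.171), C1qa (0.151), Ccng1 (0.0874), Cxcl10 (0.117), Atp6v1b2 (0.0531), Ctsd (0.0675), Gstm1 (0.0935) and Tubb3 (0.0805) were lost. With edgeR those of Mc5r (0.275), C1qa (0.214), Camp (0.316), Cma1 (0.238), Slc38a5 (0.108), Mmp13 (0.244), Skint5 (0.11), H2-M2 (0.0563) and Cps1 (0.137) were lost, and with DESeq2 those of Cma1 (0.194), Mmp13 (0.209) and Skint5 (0.258). With voom those of Kit (0.0742), Mlph (0.126), Ednrb (0.11), Cd207 (0.0517), C1qa (0.0668), Camp (0.0764), Cma1 (0.0506), Plxnc1 (0.115), Tubb3 (0.0501) and H2-M2 (0.0581) were lost. Fitting only the compared libraries ended those of Kit (0.084), Mlph (0.11), Mc5r (0.0923), C1qa (0.0847), Camp (0.108), Cma1 (0.084), Plxnc1 (0.0978), Tubb3 (0.0636) and Mmp13 (0.0726). Without the filter C1qa (0.0527), Ccng1 (0.0543), Plxnc1 (0.0538) and Cps1 (0.0522) were lost, with the stricter filter C1qa (0.0503) and Camp (0.0556), and without the 20 most abundant genes C1qa (0.0507) and Ccng1 (0.0507). Quantile normalization gave calls to Tyr (0.0173), Sox10 (0.0129), Nkg7 (0.0461) and Hspa1a (0.0456). Fitting only the compared libraries gave calls to Krt16 (0.0458), Gpx2 (0.0248), Nrg1 (0.0313) and Hspa1a, and edgeR to Krt16 (0.0356) and Gpx2 (0.048). With voom Krt16, Gpx2, Nrg1, Nkg7 and Phlda3 passed. With DESeq2 all 5 passed, as did Tyr, Sox10, Hspa1a and Mcm4. Sox10 and Mcm4 also passed without mouse 1.

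**Figure D3:**
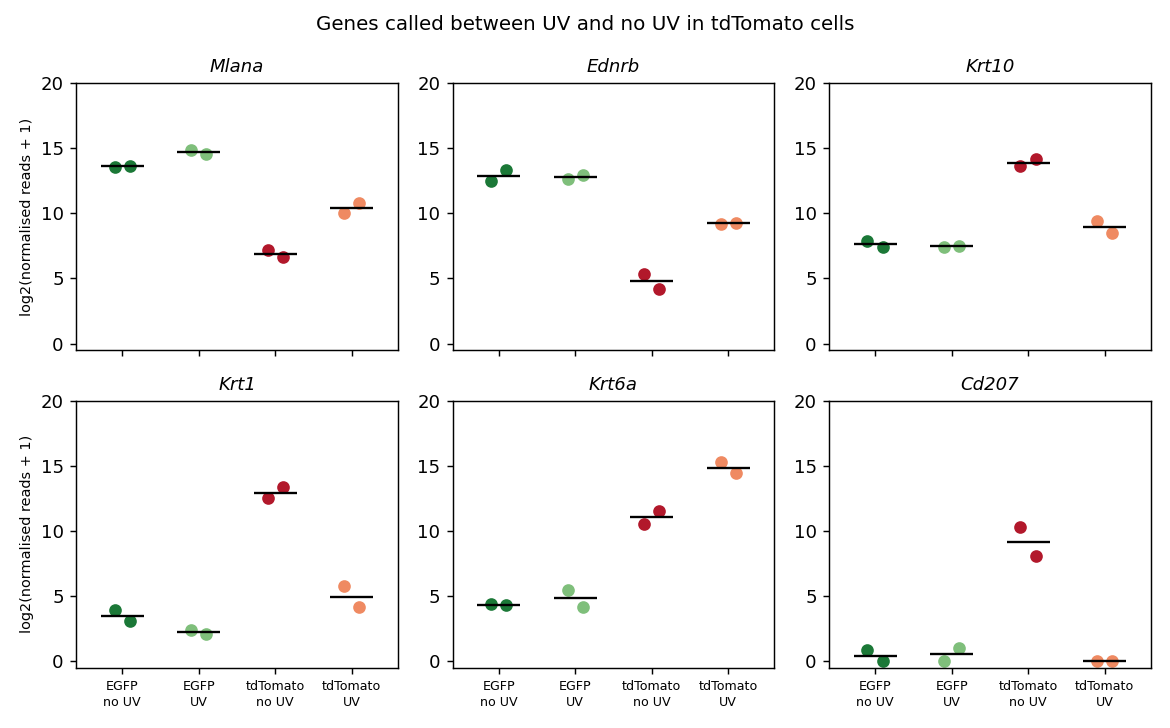
Normalized reads of genes that changed after UV in tdTomato+ cells, shown for each of the 8 libraries on a log2 scale after 1 is added.

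The UV changes of EGFP+ and tdTomato+ cells had 0 called genes in common, where 0.00631 lower genes would be shared by independent calls. Across 10770 genes with a mean of at least 50, which are not independent replicates, the 2 sets of changes correlated at r = 0.145 (Pearson) and 0.138 (Spearman), and 54.6% of genes had the same sign.

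The UV change differed between EGFP+ and tdTomato+ cells for 1 gene, Odc1. Odc1, the enzyme that begins polyamine synthesis, went from 6591 ± 289 to 2883 ± 870.3 normalized reads in EGFP+ cells and from 3190.2 ± 66.9 to 13329 ± 943 in tdTomato+ cells (n = 2 each), a difference of -3.29 ± 0.30 log2 units (adjusted p = 0.0496). Not passing were Ctsl, a lysosomal protease (-2.19 ± 0.22, adjusted p = 0.0598), Krt10 (4.78 ± 0.52, adjusted p = 0.0706), Serpine2 (-5.46 ± 0.63, adjusted p = 0.0788) and Crabp2 (-6.43 ± 0.76, adjusted p = 0.0788). Mitf stood at 0.09 ± 0.59 (adjusted p = 0.963), Tyr at -2.13 ± 0.64 (adjusted p = 0.361) and Kit at -2.83 ± 0.68 (adjusted p = 0.265). Melanin genes had the lowest p of the lists (median -2.44, 1 higher and 13 lower over the list alone, adjusted p = 1.48e-07; adjusted p = 0.566 with an estimated correlation), with UV medians of 0.11 in EGFP+ cells and 2.57 in tdTomato+ cells. Suprabasal keratinocyte genes stood at a median of 1.04 (2 higher over the list alone, adjusted p = 0.00235; adjusted p = 0.566 with an estimated correlation), T and NK cell genes at 3.48 (adjusted p = 0.00435; adjusted p = 0.566 with an estimated correlation) and Schwann cell and glia genes at -3.04 (adjusted p = 0.000497; adjusted p = 0.566 with an estimated correlation), each with 0 members called over all genes. Sebocyte genes stood at 1.64 (adjusted p = 0.00497), macrophage and dendritic cell genes at -3.94 (0.00911), lineage genes at -0.86 (0.0189), lysosome genes at -0.46 (0.0189), immediate early genes at 0.40 (0.0321) and NRF2 genes at -1.11 (0.0426). Each of these 6 lists had adjusted p = 0.566 with an estimated correlation, and cell cycle genes, at -0.99 (adjusted p = 0.0464), had adjusted p = 0.805 with an estimated correlation. In EGFP+ cells 4 of 11 T and NK cell genes had 0 reads both with and without UV, 4 more had 0 in 1 of these groups, and the list had a median UV change of 0. Sebocyte genes had a median of 0 there as well. In the macrophage, suprabasal and Schwann lists 7, 5 and 4 genes had 0 reads in 1 group. At unadjusted p under 0.05 limma had 1814 genes, and at adjusted p under 0.05 edgeR had 2, voom 3 and DESeq2 292. Odc1 lost its call, and the count was 0, in 6 of 8 fits without 1 library: no UV EGFP replicate 1, no UV EGFP replicate 2, UV EGFP replicate 2, no UV tdTomato replicate 2, UV tdTomato replicate 1 and UV tdTomato replicate 2. The call was also lost without the expression filter (0.0671), with a pseudocount of 0.1 (0.0791) and without mouse 1 (0.0719). The count was 1297 without no UV tdTomato replicate 1, 1018 without UV EGFP replicate 1, 2064 without mouse 1 (0 shared) and 14 under quantile normalization, Ctsl (0.0078), Krt10 (0.00574) and Serpine2 (0.0133) among them. With DESeq2 these 3 passed, as did Crabp2, Tyr and Kit. Ctsl and Serpine2 also passed with voom and without mouse 1, Krt10 with edgeR, Kit without mouse 1, Ctsl without the 20 most abundant genes, and Ctsl and Crabp2 with replicate number as a block. Only the melanin and suprabasal lists kept their calls in all 8 fits without 1 library, and the suprabasal list lost its call without mouse 1. The Schwann list was lost without no UV tdTomato replicate 2 and the sebocyte list without UV EGFP replicate 1. The T and NK cell list was lost without no UV EGFP replicate 1 or no UV tdTomato replicate 1.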

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

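For the first pattern the test of melanocyte RNA in tdTomato+ libraries was set before its result was seen, and for the third the test of mouse 2; the other tests of these patterns were chosen after the result was seen.

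Melanocyte genes were higher in tdTomato+ cells of UV mice. For 27 genes outside all lists, chosen as abundant in EGFP+ libraries and scarce in no UV tdTomato replicate 1, the ratio of tdTomato+ to EGFP+ levels was higher in the UV libraries than in no UV tdTomato replicate 2 alone. The median was 2.66 log2 units, against 2.91 for 13 pigment genes chosen alike, which could come from melanocyte RNA or unrecombined melanocytes and cannot be told apart from a rise in another cell type. EGFP+ cells, which leave out unrecombined melanocytes, had no like rise (median pigment gene change 0.11). Size factors centre the tdTomato+ median UV change (-0.0068 over 10767 genes with a mean of at least 50), leaving scaling open.

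Col6a1, Crabp2 and Ptn were lower in EGFP+ cells after UV. Without UV EGFP replicate 2, with the fewest genes detected, the smallest fall was -5.46, but being picked favours that. A like share of all tdTomato+ RNA in the EGFP+ libraries of mice without UV was excluded, as suprabasal keratinocyte genes reached a median of 0.190% of the tdTomato+ level there and the 3 genes 9.34% to 19.7%. A share of dermal cells cannot be told apart from a fall within melanocytes, since fibroblast genes reached a median of 1.99% with an upper quartile of 10.5%.

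Mouse 1 differed in Xist and Y-linked reads. Its lower Xist count was 477 against at most 4 elsewhere, which fits a mouse of the other sex than mice 2 to 4. Whether mouse 1 alone was behind the UV calls in tdTomato+ cells stays open. Mouse 2 lay beyond both UV libraries in 101 of 101 called genes, but the share was also 100% for as many top genes when mouse 1 was grouped with a UV library, so being picked fixes it. Without mouse 1, 60 of the 101 were called.

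The split into EGFP+ and tdTomato+ libraries was compared, by a test set before its result was seen, with all 35 splits of the 8 libraries into 4 and 4. Only the real split called as many genes (4528), and the highest count of any other was 0. All others mix both populations, which lowers the count, so chance is not decided. Only 8 splits part the libraries of every mouse, too few for a share under 0.05.

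The UV change differed between EGFP+ and tdTomato+ cells for Odc1 (-3.29). For lists the medians of that difference were as follows, and all 11 calls were lost with an estimated correlation (adjusted p = 0.566, and 0.805 for cell cycle genes). Melanin genes had -2.44, weighed as the first pattern, and no explanation was tested for the others or for Odc1. Lineage regulators had -0.86. Suprabasal keratinocyte genes had 1.04. Sebocyte genes had 1.64. Macrophage and dendritic cell genes had -3.94. T and NK cell genes had 3.48. Schwann cell and glia genes had -3.04. Cell cycle genes had -0.99. Immediate early genes had 0.40. Lysosome genes had -0.46. NRF2 targets had -1.11. In EGFP+ cells 4 of 11 T and NK cell genes had 0 reads with and without UV, and that list's median UV change was 0.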

How the results depend on the processing

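The fits with edgeR, DESeq2 and voom on recovered reads and without mouse 1 were chosen after the result was seen, and the cause of the differences below was not tested.

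For EGFP+ against tdTomato+ cells over all mice (5217 genes), leaving out 1 library gave 3463 (without UV tdTomato replicate 1) to 6594 (without UV EGFP replicate 1), and 3469 without no UV EGFP replicate 2. Without UV (3468) the range was 1398 (without no UV EGFP replicate 2) to 3659 (without no UV tdTomato replicate 1), with 2016 without no UV EGFP replicate 1 and 2107 without no UV tdTomato replicate 2. With UV (3240) it was 993 (without UV tdTomato replicate 1) to 4952 (without UV EGFP replicate 1), with 1350 without UV tdTomato replicate 2, 2055 without UV EGFP replicate 2 and 1992 when only the compared libraries were fitted.

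For UV in EGFP+ cells (3 genes) the count was 0 without no UV EGFP replicate 1, no UV EGFP replicate 2 or UV EGFP replicate 2 and 1604 without UV EGFP replicate 1. It was 16 with quantile normalization, 1 with a pseudocount of 0.1, 0 with only the compared libraries, 818 without mouse 1, 350 with DESeq2, 4 with edgeR and 0 with voom. At unadjusted p under 0.05 limma had 1875.

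For UV in tdTomato+ cells (101 genes) the count was 0 without UV tdTomato replicate 1 or 2 and 1772 without no UV tdTomato replicate 1, with 77 without no UV tdTomato replicate 2. It was 218 with quantile normalization, 29 with a pseudocount of 0.1, 183 with only the compared libraries, 2006 without mouse 1, 619 with DESeq2, 228 with voom and 91 with edgeR.

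For the difference between UV changes (1 gene) the count was 0 without no UV EGFP replicate 1, no UV EGFP replicate 2, UV EGFP replicate 2, no UV tdTomato replicate 2, UV tdTomato replicate 1 or UV tdTomato replicate 2, 1297 without no UV tdTomato replicate 1 and 1018 without UV EGFP replicate 1. It was 14 with quantile normalization, 0 without the filter, 0 with a pseudocount of 0.1, 2 without the 20 most abundant genes, 2064 without mouse 1, 2 with edgeR, 292 with DESeq2 and 3 with voom.

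With mouse as a block the counts were 5221 over all mice, 3288 without UV, 3190 with UV and 1 for the difference. Awat1 was the only named gene whose call was lost (0.0603), and 0 list calls were. With replicate number as a block, which pairs different mice across UV arms, they were 5431, 3532, 3421, 2 (UV in EGFP+), 70 (UV in tdTomato+) and 3. The lists called with either block were 23, 20, 18 and 11, and with replicate number 6 for UV in EGFP+ and 12 for UV in tdTomato+ cells.

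Values of the opposite sign were few. Tfec was 0.22 over all mice with quantile normalization. Mitf, for UV in tdTomato+ cells, was -0.0431 without no UV tdTomato replicate 1 and without mouse 1, and up to 1.01 without no UV tdTomato replicate 2. For the difference Mitf was -0.24 with quantile normalization, -0.0449 with voom, -0.43 without UV EGFP replicate 2, -0.44 without no UV tdTomato replicate 2 and -0.04 without UV tdTomato replicate 1, and up to 0.61 without no UV tdTomato replicate 1. For the cell cycle list in the difference the median was 0.40 without UV EGFP replicate 2 and -1.61 without UV EGFP replicate 1. Without no UV EGFP replicate 1 its test pointed up although the median stayed at -0.32. For the immediate early list it was -0.10 without UV EGFP replicate 2 and 0.69 without UV EGFP replicate 1.

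Of 30 lists tested, 23, 20, 18, 4, 12 and 11 passed in the 6 comparisons and 0 in each with an estimated correlation. Without 1 library the ranges were 18 to 23, 15 to 20, 16 to 21, 0 to 4, 9 to 13 and 4 to 10. Without mouse 1 the counts were 15 (all mice), 14 (no UV), 2 (UV in EGFP+) and 2 (the difference), and 2 lists passed for UV in EGFP+ cells with quantile normalization.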

Other observations

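The gene families below were chosen after their values were seen.

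Hox genes, which give cells their position along the body axis, were lower in EGFP+ than in tdTomato+ cells for 24 of 31 tested, with a median of -4.74 and 0 higher. Skint genes, which are made in keratinocytes and thymus, were lower for 11 of 11 over all mice (median -4.22), with medians of -7.36 without UV and -1.68 with UV. In tdTomato+ cells their median UV change was -5.25, and Skint5 and Skint9 passed. Because these genes are near-identical, their reads cannot be placed on 1 of them with certainty. The 4 tested genes of the Ifi20 interferon-inducible family were all lower in EGFP+ cells (median -4.72).

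Keratin genes had 25 of 45 lower and 0 higher in EGFP+ cells (median -3.74). Collagen genes had 17 of 43 lower and 2 higher (median -1.78), and their median UV change was -1.37 in EGFP+ cells (1 of 43 called) and -1.08 in tdTomato+ cells (0 called). Rab genes, which direct vesicle traffic, had 8 higher and 11 lower of 58. Serpinb protease inhibitors had 1 higher and 12 lower of 23. Potassium channel genes had 4 higher and 14 lower of 65.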
